A study of Mus musculus with 24 samples.

How the data were processed

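RNA from sorted primitive erythroid cells was hybridized to Illumina mouse bead arrays, 1 sample per array, 24 arrays on 4 slides. The main table holds 45719 probes with a mean signal, a bead error, a bead number and a detection p per array, per the file headers. The signals are the deposited intensity values, which the file headers call non-normalized. The values show otherwise for 12 arrays: the deposited intensity values of slides 2 and 4 share 1 distribution (5 quantiles differ by at most 0.417% between arrays), as after quantile normalization, while those of slides 1 and 3 differ by up to 80.7% and 28.5%. The detection p-value of each probe and array was deposited with the signals, per the file headers. The authors also deposited processed values on a scale like log2, quantile-normalized among the 18 arrays with 1 round of amplification and apart among the 6 with 2 rounds, which is read from the values since the exact transform is not stated. Which scanner software and background setting were used is not stated either.

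Signals were background-corrected with negative control levels inferred from the detection p-values, an offset of 16 was added, and the values were quantile-normalized in log2 with the neqc function of limma 3.58.1 in R 4.3.3, separately for arrays with 1 and 2 rounds. Tables were read with the packages data.table, version 1.17.8, and jsonlite, version 2.0.0. Of the probes, 29490 carry 1 gene symbol, 8 several and 16221 none, and 17583 symbols occur. Probes with no or several symbols were kept in the fits and are not named. A probe was tested if its detection p was under 0.05 on at least 3 arrays of the fit, and each gene was represented by its probe with the highest mean. The genes Hbb-y and Mki67 have no annotated probe.

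Stages were compared with linear models in limma with moderated t statistics and an intensity trend, and p was adjusted by Benjamini-Hochberg, a gene being called at an adjusted p under 0.05. One fit held E7.5 and E8.5 with 2 rounds, and one fit held the 18 arrays with 1 round, so that these stages share an estimate of the spread. Arrays with 1 and 2 rounds were compared only at E8.5, after normalization of all 24 together. The p-values measure only the spread between these samples. E8.5 replicates 4 to 6 carry the descriptions of replicates 1 to 3. After removal of each slide's mean, the arrays with the same description number correlated at -0.255, -0.0175 and -0.144, below the limit of 0.3 for shared extracts, and they were used as 6 samples. E9.5 replicate 1 carries the description of replicate 2. The signals of these 2 arrays correlated at 0.99, those of E10.5 arrays at 0.993 to 0.995, which does not settle whether they are separate samples, and by their titles they were used as 2.

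Gene lists, 35 in all, were fixed before the data were examined, together with the comparisons, the tests, the main alternatives and the rule for naming genes. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists. Counts of members are given over all genes and adjusted over the list alone. The rule names 20 genes in every comparison, the 6 largest increases and decreases among called genes whose replicates do not overlap, and up to 3 members of each called list by smallest p. The text gives all of the first 2 kinds that could be tested and part of the third. Members that moved against their list are named too and were chosen after their values were seen. Where a gene was detected on no array of a group, the change is given as at least the fold from the background level. A gene detected on some arrays of a group keeps its measured change, which is then partly against background.

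The scripts were tested on simulated data with no difference between groups except for 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold. Of these, 3%, 10.4% and 71.2% were recovered for E8.5 against E7.5, 31.3%, 85.1% and 92.4% for E9.5 against E8.5, and 29.9%, 74.6% and 93.9% for E10.5 against E9.5. For E11.5 against E10.5 the shares were 25.4%, 73.1% and 97%, for E12.5 against E11.5 28.4%, 71.6% and 97%, and for E12.5 against E8.5 47.8%, 77.6% and 98.5%. False calls numbered 0, 7, 10, 7, 9 and 10 in that order, among 56, 146, 142, 137, 140 and 159 calls. The simulated noise was independent between arrays and held no effect of slide. Real arrays with 1 round correlated at 0.31 within slides, so these shares do not cover errors from slides in comparisons that cross them.

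The alternatives were normexp background correction with an offset of 50, median scaling over probes detected on every array, cyclic loess, the authors' processed values, all 24 arrays normalized together, no filter or a stricter filter on dim probes, every probe on its own, a test against 1.5-fold, array weights, only the 2 groups compared, blocks for replicate number or slide, single slides, averaged E8.5 arrays, and leaving out each array. For lists, an estimated correlation and fry were added. After the values were seen, a block for slide 3 against slides 2 and 4, slides 2 and 4 alone, slide 3 alone, and slide 3 with no normalization between arrays were added. The bead errors and bead numbers were left out, as were probes without a symbol from all counts of genes.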

Results

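Transcript levels were measured on 24 Illumina bead arrays in primitive erythroid cells, the first red blood cells of the mouse embryo. The cells were sorted by green fluorescence from embryos in which a human epsilon-globin promoter drives a histone H2B-EGFP fusion, and they cover 6 stages a day apart, from E7.5 to E12.5. Cells of E7.5 to E9.5 came from whole embryos digested with collagenase, and cells of E10.5 to E12.5 from embryonic blood. Each replicate up to E10.5 was a pool of embryos, and each replicate at E11.5 and E12.5 a single embryo, per the labels. RNA of E7.5 (n = 3) and of E8.5 (n = 3) went through 2 rounds of amplification. RNA of E8.5 (n = 6), E9.5, E10.5, E11.5 and E12.5 (n = 3 each) went through 1 round.

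The arrays lay on 4 slides of 6. Slide 1 held the arrays with 2 rounds of amplification. Slide 2 held E8.5 replicates 1 to 3 and E9.5, slide 3 held E8.5 replicates 4 to 6 and E12.5, and slide 4 held E10.5 and E11.5. Of the 45719 probes, 12355 to 15387 were detected on each array with 1 round of amplification up to E11.5 and 13159 to 14037 on each array with 2 rounds. The 3 arrays of E12.5 had 10570, 9488 and 8542 detected probes, fewer than any other array, so transcripts near background are less often measured at that stage. The number of arrays per group limits the precision of every value.

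**Figure D1:**
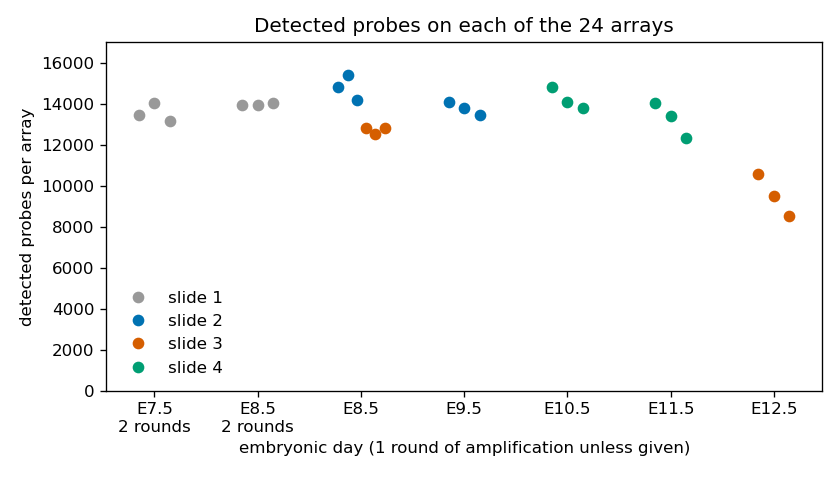
Detected probes (detection p under 0.05) on each of the 24 arrays by embryonic day, 1 point per array, coloured by slide. The E12.5 arrays had 8542 to 10570 detected probes, while the E8.5 arrays of the same slide had 12541 to 12823.

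Gene expression changed at nearly every step. Of 9412 named genes tested on the arrays with 1 round of amplification, 7289 differed between at least some of the 5 stages E8.5 to E12.5. Among these genes, 2294 had their highest mean at E8.5, 610 at E9.5, 736 at E10.5, 853 at E11.5 and 2796 at E12.5. From one day to the next, 1824 genes changed between E8.5 and E9.5, 197 between E9.5 and E10.5, 1086 between E10.5 and E11.5 and 4737 between E11.5 and E12.5. The last step crosses slides, and under cyclic loess it gave 2166 genes against 2243 between E8.5 and E9.5. Changes below are log2 differences of the later minus the earlier stage with their standard errors (SE).

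Between E7.5 and E8.5 (n = 3 each, 2 rounds of amplification), members of the hemoglobin, heme, iron and red cell membrane lists rose, and some progenitor, endothelial and epiblast genes fell. No list passed with an estimated correlation (adjusted p = 0.19 to 0.26 for the called ones). Slc4a1, which encodes the anion exchanger of the red cell membrane, rose by 6.94 ± 0.75 (adjusted p = 0.0034). The embryonic alpha globin Hba-x rose by 5.96 ± 1.3 (adjusted p = 0.029), and Alas2, the erythroid enzyme that starts heme synthesis, by 3.01 ± 0.29 (adjusted p = 0.0022). Gata2, a transcription factor of blood progenitors, fell by 4.65 ± 0.41 (adjusted p = 0.0019). In all, 489 genes were higher and 645 lower at E8.5 out of 8568 tested. The comparison asks which transcripts mark the first day of the lineage. Both groups lay on slide 1.

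Other large increases were Mgst3 (4.68 ± 0.61), Hba-a1 (4.68 ± 0.83) and Kel (4.34 ± 0.34), and Hif3a was at least 26.7-fold higher, not being detected on any E7.5 array. The value of Hif3a comes from the brighter of its probes, and with 1 E8.5 array left out the other probe was used, with changes of 0.42, 0.03 and 0.22 without replicates 1, 2 and 3 (adjusted p = 0.33, 0.96 and 0.74). The largest decreases besides Gata2 were Slc32a1 (-4.75 ± 0.29), Etl4 (-4.63 ± 0.79), Ptgis (-4.08 ± 0.73), Rpp25 (-3.97 ± 0.77) and Rspo3 (-3.88 ± 0.73). The progenitor genes Myb, Runx1 and Kit fell by 1.84 ± 0.28, 3.32 ± 0.72 and 0.87 ± 0.22. Ptgis, Rpp25 and Runx1 were detected on 1 of 3 E8.5 arrays. Hbb-bh1 (1.16), Nfe2 (1.04), Epor (0.82), Tfrc (0.59), Klf1 (0.40), Tal1 (0.08) and Gata1 (-0.42) did not pass.

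E7.5 replicate 2 lay between replicates 1 and 3 for 99.8% of the 404 probes that differed more than 4-fold between those arrays. Whether it held material of both is not settled. If it did, E7.5 had fewer than 3 independent samples, and the p-values and counts of this comparison with all arrays would be too strong. Hba-x read 4.77, 9.15 and 10.38 on E7.5 replicates 1, 2 and 3. Without E7.5 replicate 2, 217 genes passed (99 higher, 118 lower), 216 of which had passed in the same direction with it. Hba-x (adjusted p = 0.076), Hba-a1 (0.053), Etl4 (0.062), Ptgis (0.072), Rpp25 (0.087), Rspo3 (0.087), Myb (0.06), Runx1 (0.11) and Kit (0.25) then no longer passed. Leaving out E7.5 replicate 1, E8.5 replicate 2 or E8.5 replicate 3 gave 647, 471 and 722 genes. Hba-x, Hba-a1, Ptgis, Rpp25, Rspo3, Runx1 and Kit also missed the threshold without E8.5 replicate 2 (adjusted p = 0.092, 0.058, 0.055, 0.066, 0.063, 0.089 and 0.14). Without E8.5 replicate 3, so did Hba-x (0.083), Rspo3 (0.059) and Kit (0.08), and without E8.5 replicate 1, Hba-x (0.06), Runx1 (0.073) and Kit (0.062). Runx1 and Kit missed it without E7.5 replicate 3 (0.064 and 0.067) and Kit without E7.5 replicate 1 (0.14).

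Among the gene lists fixed beforehand, 5 red cell lists were called upwards, and erythroid transcription factors were not (1 of 15 up, adjusted p = 0.36). All 4 adult globins tested rose (median 3.25, 4 adjusted over the list alone, adjusted p = 2.2e-05), with Hbb-bs at 3.15 ± 0.29 and Hbb-bt at 3.35 ± 0.21. Their near-identical copies make single adult globin genes uncertain. In heme synthesis 8 of 13 members rose and none fell (9 up and 1 down adjusted over the list alone, adjusted p = 1e-06), among them Slc6a9 (1.22 ± 0.12) and Ppox (1.94 ± 0.26). Red cell membrane and skeleton had 12 of 16 members up (13 up and 1 down alone, adjusted p = 5.3e-08), for example Add1 (1.99 ± 0.16), while Aqp1 was at least 3.58-fold lower. Red cell enzymes had 6 of 13 up (9 alone, adjusted p = 7e-05), with Gpx1 at 1.84 ± 0.13. For these 4 lists the adjusted p = 0.19 with an estimated correlation. Iron uptake and handling had 4 members up and 1 down of 14 (the same numbers alone, adjusted p = 0.036), led by Slc25a37 (3.25 ± 0.18), with Pcbp1 down (-1.28), and adjusted p = 0.26 with an estimated correlation. Without E7.5 replicate 1, E8.5 replicate 1 or E8.5 replicate 2 its adjusted p was 0.09, 0.14 and 0.26. Pcbp1 lost its call whichever of the 6 arrays was left out (adjusted p = 0.051 to 0.17).

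Of 13 progenitor genes 8 fell (9 alone, median -1.14; adjusted p = 0.00035). In TGF-beta and BMP signalling 6 of 20 fell (9 alone, adjusted p = 0.0012), with Smad4 at -1.95 ± 0.22. In adhesion 6 of 18 fell (7 alone, adjusted p = 0.011), with Cd9 at -1.14 ± 0.16, and in ribosome assembly 3 of 23 fell (3 alone, adjusted p = 0.01). Its member Nop58 fell by 1.28 ± 0.21 and did not pass without E7.5 replicate 2 (adjusted p = 0.071). With an estimated correlation the adjusted p = 0.19 for each of these 4 lists. The respiratory chain list was called upwards (4 up, 1 down of 30, the same alone, adjusted p = 0.032, adjusted p = 0.19 with an estimated correlation). Its smallest p belonged to a member that fell, Cox5a (-0.78 ± 0.16), which lost its call without E7.5 replicate 2, E7.5 replicate 3 or E8.5 replicate 2 (adjusted p = 0.13, 0.062 and 0.068). The list was not called without E7.5 replicate 1 or 2 (adjusted p = 0.098 and 0.076).

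Markers of other cell types moved as well. Endothelial markers fell (4 down, 1 up of 14; 7 and 1 alone, adjusted p = 0.021, adjusted p = 0.24 with an estimated correlation), with Cdh5 at -2.25 ± 0.29 and Cldn5 up (1.73), and were not called without E7.5 replicate 1 or E8.5 replicate 1 (adjusted p = 0.063 and 0.06). Laptm5 (-2.81 ± 0.30) and Spi1, the called pair among 3 macrophage and leukocyte markers (2 alone, adjusted p = 0.014), fell, and the list could not be tested without any one E7.5 array. Cldn5 lost its call without E7.5 replicate 1, 2 or 3 or E8.5 replicate 1 or 2 (adjusted p = 0.087, 0.17, 0.082, 0.087 and 0.13), and Spi1 without E8.5 replicate 2 or 3 (0.053 and 0.057). Epiblast markers fell (2 of 4, 2 alone, adjusted p = 0.021), with Dnmt3b at -1.69 ± 0.17. Without E7.5 replicates 1, 2 and 3 or E8.5 replicate 3 the epiblast list had adjusted p = 0.34, 0.21, 0.067 and 0.073. Visceral endoderm markers rose (4 of 13, 7 alone, median 1.75; adjusted p = 0.0019), with Dab2 at 2.82 ± 0.45 (adjusted p = 0.058 without E7.5 replicate 2). Immediate early genes rose (5 of 14; 6 up and 1 down alone, adjusted p = 0.01), with Dusp1 at 2.65 ± 0.18, and were not called without E8.5 replicate 1 (adjusted p = 0.17). With an estimated correlation the adjusted p = 0.19 for macrophage, epiblast and immediate early genes and 0.26 for visceral endoderm. Megakaryocyte, mesenchyme, neural and cardiac markers were not called (adjusted p = 0.58, 0.85, 0.69 and 0.69). With no normalization between arrays, 539 genes were higher and 465 lower (53.7% higher against 43.1%), and Kit, Pcbp1 and Cox5a did not pass (adjusted p = 0.071, 0.052 and 0.057).

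Between E8.5 (n = 6) and E9.5 (n = 3), members of the red cell membrane, adult globin, heme and iron lists rose while members of the glycolysis, ribosome assembly, immediate early and visceral endoderm lists fell. No list passed with an estimated correlation (adjusted p = 0.13 to 0.35 for the called ones). The adult beta globin Hbb-bs rose by 1.60 ± 0.19 (adjusted p = 2.3e-06), Alas2 by 0.97 ± 0.16 (adjusted p = 1e-04) and the Rh-associated glycoprotein Rhag by 2.11 ± 0.27 (adjusted p = 5.1e-06). The glycolytic enzymes Pkm and Hk2 fell by 2.12 ± 0.18 and 2.39 ± 0.23 (adjusted p = 1.3e-07 and 4.9e-07). Of 9412 genes, 700 were higher and 1124 lower. The question is what changes in the cells around the day on which they enter the circulation.

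The largest increases were Krt15 (3.18 ± 0.20), B4galnt1 (2.63 ± 0.33), Septin12 (2.61 ± 0.33), Mreg (2.59 ± 0.35), Ripor3 (2.56 ± 0.24) and Hmbox1 (2.55 ± 0.33), and within slide 2 these came to 3.05, 1.90, 1.87, 1.79, 2.10 and 1.80. The largest decreases were Ddah1 (-3.24 ± 0.29), Ifitm2 (-2.62 ± 0.21), Fscn1 (-2.61 ± 0.29), Prtg (-2.57 ± 0.25), Atp2a3 (-2.56 ± 0.21) and Gsta4 (-2.51 ± 0.22), or -3.16, -2.73, -2.03, -2.14, -2.20 and -2.14 within slide 2. Krt15 was detected on 1 of 6 E8.5 arrays, so its change is against values near background. Kit was at least 3.36-fold lower, Gata2 at least 1.96-fold and Runx1 at least 1.63-fold, none being detected on the E9.5 arrays. Slc4a1 rose by 1.04 ± 0.27 (adjusted p = 0.068 without E9.5 replicate 3). Klf1 rose by 1.09 ± 0.27 (adjusted p = 0.0051), or by 0.61 with slide as a block or within slide 2 (adjusted p = 0.061 and 0.08). Hbb-bh1 (-0.37), Hba-x (-0.29), Hba-a1 (-0.28), Gata1 (0.35), Nfe2 (1.00), Tal1 (0.09), Myb (-0.20), Epor (0.49), Tfrc (0.49) and Cdkn1b (0.04) did not pass, but Tfrc did with slide as a block or within slide 2 (adjusted p = 0.026 and 0.047).

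The E8.5 arrays lay on slides 2 and 3 and the E9.5 arrays on slide 2. With slide as a block 1297 genes passed, 1086 of them called in the same direction without it, and within slide 2 alone 1214 passed. Leaving out E9.5 replicate 2 gave 1103 genes. Median scaling in place of quantile normalization shifted the median of all genes by -0.276 and gave 660 higher and 2469 lower genes (21.1% higher against 38.4%).

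In the red cell membrane list 9 of 16 members rose and none fell (10 alone, median 0.78; adjusted p = 1.8e-05, 1.4e-06 within slide 2), with Kel at 1.53 ± 0.21. Of 4 adult globins 3 rose (3 alone, adjusted p = 0.0064, 0.011 within slide 2), with Hbb-bt at 1.47 ± 0.20. For both lists the adjusted p = 0.13 with an estimated correlation. Heme synthesis had 6 members up and 1 down of 15 (the same alone, adjusted p = 0.012, but 0.066 within slide 2), with Fech at 1.42 ± 0.24 and Alas1 down (-0.55), and adjusted p = 0.26 with an estimated correlation. Iron uptake had 3 of 13 up (4 alone, adjusted p = 0.015, 0.018 within slide 2), with Tfr2 at 1.01 ± 0.20, and adjusted p = 0.17 with an estimated correlation. In erythropoietin and JAK-STAT signalling 7 of 19 rose and 2 fell (9 and 3 alone, adjusted p = 0.044, 0.027 within slide 2), with Osm at 1.78 ± 0.24 and Cish at 1.65 ± 0.27, and adjusted p = 0.25 with an estimated correlation. Red cell enzymes were not called (4 up and 2 down of 14, median 0.02; adjusted p = 0.67). The erythropoietin list was not called without E8.5 replicate 1, 2 or 3 or E9.5 replicate 1 or 3 (adjusted p = 0.097, 0.061, 0.053, 0.084 and 0.07). Alas1 lost its call without E8.5 replicate 2 or 3 or E9.5 replicate 1, 2 or 3 (adjusted p = 0.07, 0.069, 0.067, 0.15 and 0.1).

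Glycolysis and glucose uptake fell in 8 of 17 members, with Pdk1 up (0.75; 10 down and 1 up alone, adjusted p = 4.7e-05, 0.00018 within slide 2, adjusted p = 0.13 with an estimated correlation). Ribosome assembly fell in 7 of 22 (7 alone, adjusted p = 0.0029, 2.6e-05 within slide 2, adjusted p = 0.26 with an estimated correlation), with Nop58 at -1.04 ± 0.20. DNA replication fell in 5 of 24 (5 alone, adjusted p = 0.041, 0.0063 within slide 2, adjusted p = 0.35 with an estimated correlation), with Ccne1 at -1.43 ± 0.16, and was not called without E8.5 replicate 1, 2 or 3 or E9.5 replicate 2 (adjusted p = 0.084, 0.058, 0.077 and 0.15). TGF-beta and BMP signalling fell in 4 of 20 with Ltbp1 up (0.39; the same numbers alone, adjusted p = 0.043, adjusted p = 0.35 with an estimated correlation), with Acvr2b at -1.69 ± 0.19. This list was not called with slide as a block or within slide 2 (adjusted p = 0.15 each), nor without E8.5 replicate 2 or 4 or E9.5 replicate 1 or 3 (0.069, 0.07, 0.074 and 0.056). Ltbp1 lost its call without any one array except E8.5 replicate 3 (adjusted p = 0.053 to 0.19), and came to 0.24 with slide as a block or within slide 2 (0.32 and 0.3) and 0.17 under median scaling (0.46). Pdk1 lost its call without E9.5 replicate 3 (0.11), and came to 0.58 with slide as a block or within slide 2 (adjusted p = 0.099 and 0.05). Immediate early genes fell in 6 of 14 (7 alone, adjusted p = 0.00061, 0.00054 within slide 2, adjusted p = 0.26 with an estimated correlation), with Jun, detected on 1 of 3 E9.5 arrays, at -1.01 ± 0.18. Visceral endoderm markers fell in 9 of 13 (10 alone, median -0.97; adjusted p = 0.00021, 0.00054 within slide 2, adjusted p = 0.35 with an estimated correlation), with Rhox5 at least 1.94-fold lower. The other marker lists were not called: endothelial, macrophage, megakaryocyte, mesenchyme, epiblast, neural and cardiac markers had adjusted p = 0.43, 0.55, 0.16, 0.39, 0.47, 0.55 and 0.94.

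Between E9.5 and E10.5 (n = 3 each), few genes changed, with 140 higher and 57 lower of 9412. An iron exporter, cell cycle inhibitors and lamin A were among the increases. The iron exporter Slc40a1 rose by 2.00 ± 0.28 (adjusted p = 0.00036), the inhibitor Cdkn2c by 1.87 ± 0.21 (adjusted p = 5.1e-05) and the lamin gene Lmna by 1.62 ± 0.22 (adjusted p = 0.00036). Hk2 fell further, by 1.72 ± 0.27 (adjusted p = 0.0013). The comparison spans the change from whole embryos to blood as the source of the cells, and E9.5 lay on slide 2 and E10.5 on slide 4, so stage, source and slide cannot be told apart.

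The other large increases were Pdzk1ip1 (2.38 ± 0.24), Plek2 (2.09 ± 0.26), Hemgn (1.71 ± 0.28) and Rgcc (1.67 ± 0.22), and the other large decreases Plxnd1 (-2.26 ± 0.26), Igf2bp1 (-2.04 ± 0.24), Ddah1 (-1.92 ± 0.34), Cd63 (-1.63 ± 0.25) and Mdk (-1.51 ± 0.28; adjusted p = 0.057 without E10.5 replicate 2). Of the genes given in every comparison none passed. Alas2 came to 0.68 (adjusted p = 0.062), Epor to 0.60, Tal1 to 0.53, Tfrc to 0.48, Nfe2 to 0.47, Hba-x to 0.29 and Hbb-bh1 to -0.34, and Hba-a1, Hbb-bs, Gata1, Gata2, Klf1, Kit, Myb, Runx1, Slc4a1 and Cdkn1b lay between -0.17 and 0.19. With slide as a random block 18 genes passed, and Hemgn, Ddah1, Mdk, Icam4, Slc25a38, Fth1 and Wdr43 did not (adjusted p = 0.062, 0.13, 0.13, 0.24, 0.19, 0.13 and 0.22). Leaving out E9.5 replicate 1 or 2 gave 56 and 61 genes, and leaving out E10.5 replicate 1, 2 or 3 gave 123, 56 and 52. Other settings raised the count, to 581 with only the 2 groups in the fit, 507 with averaged E8.5 arrays and 817 on slides 2 and 4 alone. The main fit takes its spread from all 18 arrays and holds the E8.5 arrays of slides 2 and 3 as 1 group. The count of this step therefore depends on that shared spread. Under median scaling 183 genes were higher and 156 lower (54% higher against 71.1%).

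List members mostly shifted by amounts that did not pass one by one. Red cell membrane genes had a median of 0.49 with 2 of 16 up (8 alone, adjusted p = 6e-07, adjusted p = 0.054 with an estimated correlation), Icam4 rising by 1.32 ± 0.25 with all arrays but not without E9.5 replicate 1 or E10.5 replicate 2 (adjusted p = 0.057 and 0.053). Heme synthesis had 1 of 15 up (4 alone, median 0.30; adjusted p = 0.00059, adjusted p = 0.084 with an estimated correlation), Slc25a38 (1.04 ± 0.19; adjusted p = 0.051 without E10.5 replicate 3). Iron uptake and handling had 2 of 13 up (3 alone, adjusted p = 0.0015, adjusted p = 0.054 with an estimated correlation), Slc40a1 and the ferritin gene Fth1 (1.19 ± 0.21). Fth1 came to 0.79 under median scaling and 0.72 under cyclic loess (adjusted p = 0.065 and 0.11). Red cell enzymes had 1 of 14 up (4 alone, median 0.44; adjusted p = 0.00066, adjusted p = 0.062 with an estimated correlation). Cell cycle inhibitors had 3 of 16 up (5 alone, adjusted p = 0.00064, 0.031 with an estimated correlation) and antioxidant genes 1 of 15 (2 alone, median 0.42; adjusted p = 0.0015, 0.031 with an estimated correlation).

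The DNA replication list was called upwards with a median of 0.22 and 1 of 24 members up (5 alone, adjusted p = 0.0015, adjusted p = 0.13 with an estimated correlation). The autophagy list was called upwards with a median of 0.14, but none of its 18 members passed (5 alone, adjusted p = 0.0022, adjusted p = 0.13 with an estimated correlation). Mitosis genes had a median of 0.20 with 1 of 23 up (1 alone, adjusted p = 0.036, adjusted p = 0.54 with an estimated correlation) and were not called without E9.5 replicate 3 or E10.5 replicate 3 (adjusted p = 0.15 and 0.11). Nuclear condensation and lamina had 2 of 16 up (3 up and 1 down alone, adjusted p = 0.038, adjusted p = 0.15 with an estimated correlation), and was not called without E9.5 replicate 3 or E10.5 replicate 1 or 3 (adjusted p = 0.075, 0.052 and 0.069). Ribosome assembly fell by a median of 0.41 with 1 of 22 called (6 alone, adjusted p = 6e-07, adjusted p = 0.057 with an estimated correlation). That member, Wdr43 (-1.0 ± 0.24), lost its call whichever of the 6 arrays except E9.5 replicate 3 was left out (adjusted p = 0.067 to 0.19). No marker list was called, the smallest adjusted p being 0.097 for endothelial markers, which passed downwards with slide as a random block (0.0037), with the added block for the deposit batch (0.027) and on slides 2 and 4 alone (0.036), with 1 of 12 members down.

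Between E10.5 and E11.5 (n = 3 each, both on slide 4), ribosome assembly genes fell across the list, some metabolic genes fell, and cell cycle inhibitors rose. Of these lists, glycolysis, the TCA cycle and the respiratory chain had adjusted p = 0.25, 0.31 and 0.36 with an estimated correlation. In ribosome assembly 17 of 22 members fell and none rose (21 alone, median -1.13; adjusted p = 2.1e-18, 0.0032 with an estimated correlation, 1.9e-13 within slide 4), among them Nop58 (-1.72 ± 0.24) and Rrp9 (-1.38 ± 0.19). Lactate dehydrogenase A, Ldha, fell by 2.41 ± 0.27 (adjusted p = 1.3e-05). The inhibitors Cdkn2d and Cdkn2c rose by 1.59 ± 0.20 and 1.52 ± 0.21 (adjusted p = 3.9e-05 and 1e-04). Of 9412 genes 402 were higher and 684 lower. The comparison asks how circulating cells change over a day, from pools of embryos to single embryos.

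The largest increases were Hbb-b2 (3.13 ± 0.54), Gdf1 (2.26 ± 0.23), Ypel5 (2.16 ± 0.23), Sirt3 (2.16 ± 0.33) and Ypel4 (2.00 ± 0.17), and Rsad2 was at least 7.91-fold higher. Besides Ldha the largest decreases were Psat1 (-2.33 ± 0.34), Dctd (-1.99 ± 0.23), Mcrip2 (-1.93 ± 0.22), Ccdc86 (-1.90 ± 0.22) and Srm (-1.83 ± 0.24). Each of these has the same value within slide 4 by construction, since both stages lie on that slide alone. The transferrin receptor gene Tfrc fell by 0.84 ± 0.20 (adjusted p = 0.0098; 0.052 without E10.5 replicate 3). Nfe2 (0.76), Hbb-bs (0.55), Gata1 (0.29), Tal1 (0.27), Epor (0.21), Alas2 (0.12), Hbb-bh1 (0.11), Hba-a1 (-0.45), Slc4a1 (-0.47) and Hba-x (-0.67) did not pass, nor did Gata2, Klf1, Kit, Myb, Runx1 and Cdkn1b, which lay between -0.17 and 0.14. Within slide 4 Hba-x, Hba-a1, Slc4a1 and Nfe2 passed (adjusted p = 0.00088, 0.0092, 0.0092 and 0.0027).

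Within slide 4 alone 2852 genes passed. Leaving out E10.5 replicate 1 or 2 gave 430 and 591 genes, and leaving out E11.5 replicate 1 or 2 gave 607 and 564. Median scaling shifted the median of all genes by -0.128 and gave 424 higher and 1159 lower genes (26.8% higher against 37%).

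Cell cycle inhibitors had 5 of 16 up (7 alone, median 0.59; adjusted p = 2.2e-06, 0.0032 with an estimated correlation), with Ccng2 at 1.65 ± 0.18. Red cell membrane genes had 5 of 16 up (6 alone, adjusted p = 0.00078, adjusted p = 0.25 with an estimated correlation), with Cd47 at 1.42 ± 0.24. Glycolysis fell in 4 of 17 (5 alone, adjusted p = 0.0043, adjusted p = 0.25 with an estimated correlation), with Pkm at -1.33 ± 0.21, and the respiratory chain in 3 of 30 (3 alone, adjusted p = 0.0053, adjusted p = 0.36 with an estimated correlation), with Cox5a at -1.12 ± 0.20. The TCA cycle fell by a median of 0.44 with 1 of 16 called (2 alone, adjusted p = 0.015, adjusted p = 0.31 with an estimated correlation; 0.074 without E11.5 replicate 2). DNA replication fell in 2 of 24 (2 alone, adjusted p = 0.031, adjusted p = 0.36 with an estimated correlation), with Ccne1 at -0.85 ± 0.18, and was not called without E10.5 replicate 2 or 3 or E11.5 replicate 1 or 2 (adjusted p = 0.055, 0.097, 0.057 and 0.084).

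Cytosolic ribosomal proteins fell by a median of 0.23 with 2 of 24 called (2 alone, adjusted p = 0.028, adjusted p = 0.58 with an estimated correlation), Rps19 being at least 1.97-fold lower, but under cyclic loess their median relative to all genes was 0.02 (adjusted p = 0.39). Without E10.5 replicate 1 or E11.5 replicate 1 or 2 the list had adjusted p = 0.06, 0.057 and 0.063. The proteasome and ubiquitin list was called downwards (3 of 22 down, 8 alone, adjusted p = 0.02, adjusted p = 0.25 with an estimated correlation), yet its ubiquitin-conjugating enzymes Ube2h and Ube2l6 rose by 1.11 ± 0.18 and 1.30 ± 0.22, and it was not called without E10.5 replicate 1 or E11.5 replicate 1 (adjusted p = 0.06 and 0.057). All 9 called lists passed within slide 4 as well, with adjusted p of at most 0.016. That fit compares the same arrays with another estimate of the spread and another set of genes tested, so it is no check on slide. No marker list was called, with adjusted p from 0.57 for neural to 0.91 for visceral endoderm markers.

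**Figure D2:**
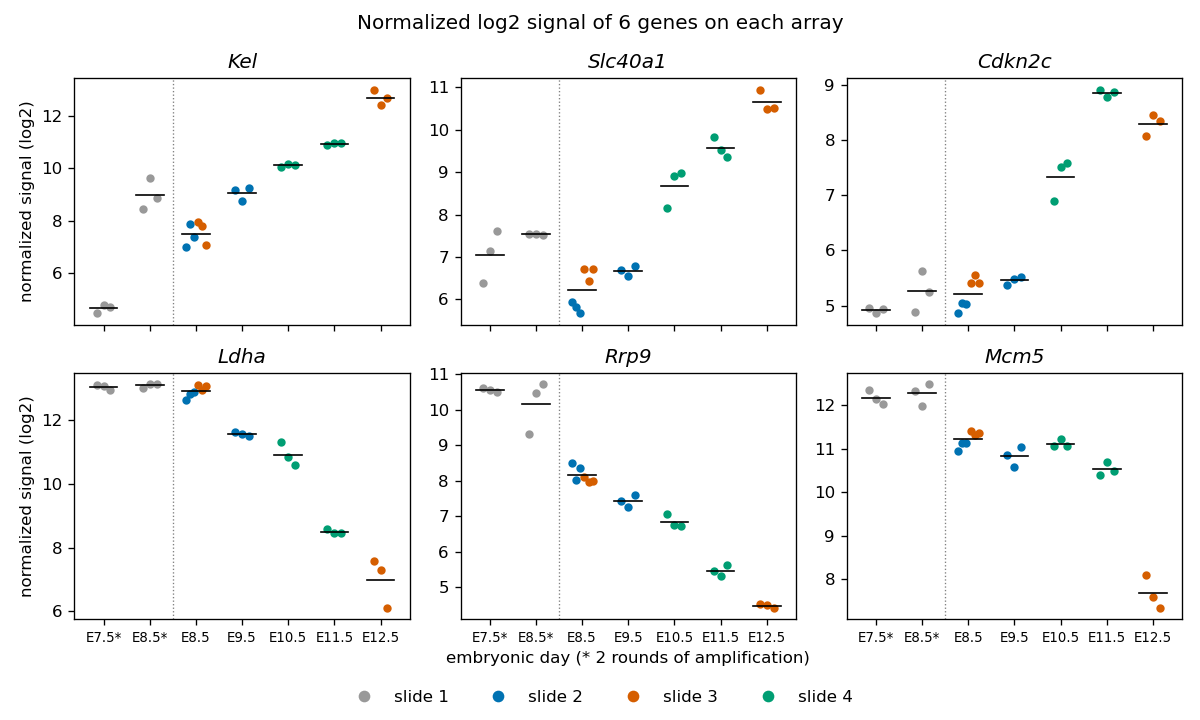
Normalized log2 signal of Kel, Slc40a1, Cdkn2c, Ldha, Rrp9 and Mcm5 on each array by embryonic day, coloured by slide, with a bar at each group's mean; asterisks mark the arrays with 2 rounds of amplification. The mean of Kel went from 7.52 at E8.5 to 12.70 at E12.5, that of Ldha from 12.91 to 6.98, and that of Mcm5 lay at 10.52 to 11.22 from E8.5 to E11.5 and at 7.67 at E12.5.

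Between E11.5 and E12.5 (n = 3 each), DNA replication and mitosis genes fell and 10 of 18 autophagy genes rose. In DNA replication 21 of 24 members fell and none rose (22 alone, median -2.36; adjusted p = 3.2e-15, 0.0035 with an estimated correlation), with Mcm6 at -2.98 ± 0.19 and Rrm1 at least 8.09-fold lower. In mitosis 18 of 23 fell and only Bub1 rose (0.91, but -0.16 under cyclic loess; the same numbers alone, adjusted p = 2.7e-07, adjusted p = 0.26 with an estimated correlation), with Aurkb at -2.64 ± 0.23 and Top2a at -2.96 ± 0.29. Hmox1, the heme-degrading enzyme, rose by 5.14 ± 0.32 (adjusted p = 1.6e-10). Of 9412 genes 2508 were higher and 2229 lower. The comparison asks what the last day of the series brings, when the cells are expected to be leaving the cell cycle.

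E11.5 lay on slide 4 and E12.5 on slide 3, so that stage and slide cannot be told apart in this comparison without the E8.5 arrays, which lie on slides 2 and 3. A block for slide 3 against slides 2 and 4, added after the values were seen, gave 3722 genes, 2990 of them called in the same direction without it. The block takes slides 2 and 4 as alike, and they share 1 distribution in the deposited signals. That does not exclude differences of single probes. Between the E8.5 arrays of slides 2 and 3, 3664 genes differed in the authors' values, which share 1 distribution too. Any difference between slides 2 and 4 therefore remains in the values with the block. With the block the 4 called lists had adjusted p = 9.4e-20 for DNA replication, 2.7e-09 for mitosis, 0.00071 for ribosome assembly and 0.0084 for autophagy. Median scaling shifted the median of all genes by 1.90 and gave 7350 higher and 561 lower genes (92.9% higher against 52.9%). Relative to that shift DNA replication and mitosis lay at -3.0 and -2.86.

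The largest increases besides Hmox1 were Rsad2 (4.89 ± 0.45), Col4a2 (4.11 ± 0.38), Tbcel (4.06 ± 0.26), Hbq1a (3.92 ± 0.25) and Hspb8 (3.43 ± 0.22), and with the added block these came to 4.9, 3.40, 3.44, 3.99 and 3.31. The largest decreases were H2ac15 (-4.72 ± 0.38), H2ac12 (-3.77 ± 0.46), Selenoh (-3.73 ± 0.44) and Tmpo (-3.64 ± 0.43), with Lig1 at least 11.3-fold lower. With the added block H2ac15, H2ac12, Selenoh and Tmpo came to -3.59, -2.20, -2.01 and -2.36. Col4a2 was detected on 1 of 3 E11.5 arrays and Selenoh on 1 of 3 E12.5 arrays.

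Alas2 rose by 1.12 ± 0.19 and Cdkn1b by 1.05 ± 0.26, or by 1.10 and 1.20 with the added block, Cdkn1b coming to -0.07 under cyclic loess. Hba-a1 (1.03 ± 0.25), Hbb-bh1 (0.78 ± 0.26), Hba-x (0.71 ± 0.24), Slc4a1 (1.29 ± 0.32) and Tal1 (1.17 ± 0.25) rose, but did not pass with that block (0.73, 0.32, 0.50, 0.90 and 0.60; adjusted p = 0.078, 0.44, 0.22, 0.096 and 0.091). Hbb-bh1 did not pass without E11.5 replicate 2 (adjusted p = 0.057), nor Hba-x without E11.5 replicate 1 or E12.5 replicate 3 (0.068 and 0.052). Klf1 fell by 0.75 ± 0.31 (adjusted p = 0.047) but came to 0.22 with the added block, 0.39 under cyclic loess, -0.48 with slide as a random block (0.37) and -0.21 under median scaling (0.5), and it lost its call without any one array of E11.5 or without E12.5 replicate 2 or 3 (adjusted p = 0.063 to 0.16). Hbb-bs (0.07), Gata1 (-0.40), Gata2 (0.10), Nfe2 (-0.07), Kit (0.07), Myb (-0.08), Runx1 (-0.03), Epor (-0.46) and Tfrc (0.04) did not pass, though Nfe2 and Kit came to 1.84 and -0.75 with the added block (adjusted p = 8.5e-05 and 0.017). The block subtracts the difference of slide 3 from slide 2 at E8.5, which was -1.91 for Nfe2. Kit was detected on no E12.5 array, so its value with the block rests on that subtraction and is no measured fall.

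Ribosome assembly fell in 15 of 22 members (17 alone, median -0.95; adjusted p = 0.00019, adjusted p = 0.26 with an estimated correlation), with Nop56 at -2.23 ± 0.35, and under median scaling its median relative to all genes was -1.50, but under cyclic loess it turned to 0.29 (adjusted p = 0.15). Autophagy and mitochondrial clearance rose in 10 of 18 (10 up and 1 down alone, median 1.04; adjusted p = 0.012, adjusted p = 0.28 with an estimated correlation), with Sqstm1 at 2.26 ± 0.22 and Gabarapl1 at 2.36 ± 0.24. Its adjusted p was 0.054 without E12.5 replicate 1 and 0.48 under median scaling. With all arrays 4 lists were called, and 12 and 8 lists were called without E12.5 replicate 2 and replicate 3. Red cell membrane and heme genes had medians of 0.85 and 0.51 and were not called (adjusted p = 0.05 and 0.26). No marker list was called, with adjusted p from 0.19 for cardiac to 0.95 for mesenchyme markers.

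**Figure D3:**
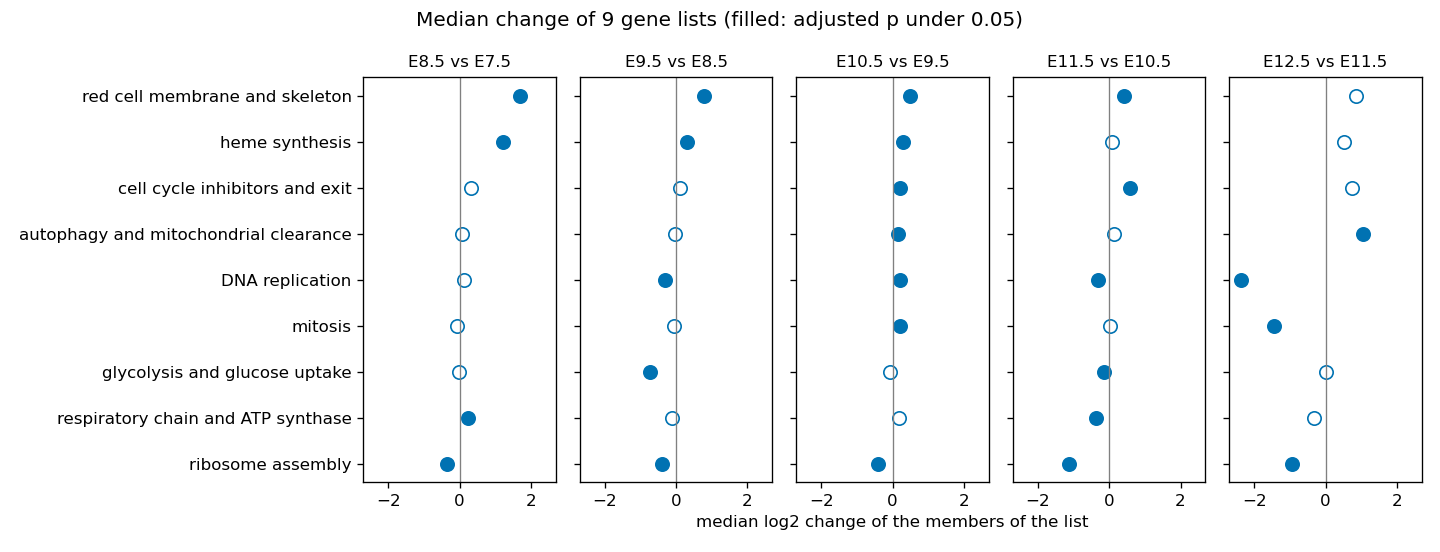
Median log2 change of the members of 9 gene lists in each comparison of consecutive stages, filled where the list's adjusted p was under 0.05. DNA replication fell by a median of 2.36 at E12.5 and ribosome assembly by 1.13 at E11.5; the ribosome assembly median of -0.95 at E12.5 turned to 0.31 under cyclic loess, while under median scaling it was 0.40, or -1.50 relative to all genes.

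Between E8.5 (n = 6) and E12.5 (n = 3), the whole course left 3196 genes higher and 3577 lower of 9412, with members of the red cell membrane, heme, iron and cell cycle inhibitor lists up and members of the replication, ribosome and energy metabolism lists down. DNA replication, ribosome assembly and cell cycle inhibitors stayed called with an estimated correlation, and the other called lists did not (adjusted p = 0.064 to 0.31). Kel, a red cell surface protease, rose by 5.19 ± 0.21 (adjusted p = 9.5e-15) and Slc40a1 by 4.44 ± 0.24 (adjusted p = 5.6e-13). Ldha fell by 5.92 ± 0.24 (adjusted p = 7e-15). All 22 ribosome assembly genes fell (22 alone, median -2.79; adjusted p = 1.1e-11, 0.014 with an estimated correlation). The comparison gives the net change over the stages measured with 1 round of amplification. Slide 3 holds both stages, and there 5626 genes passed. With slide as a block 6398 passed.

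Rsad2 was at least 239-fold higher, and Pdzk1ip1 (7.73 ± 0.21), Hbb-b2 (5.96 ± 0.47), Igtp (5.81 ± 0.18), Ypel5 (5.72 ± 0.20) and Gdf1 (5.34 ± 0.20) rose, with 7.74, 6.32, 5.82, 5.63 and 5.41 within slide 3. Ddah1 was at least 31.3-fold and Hk2 at least 19.8-fold lower, and Mif (-5.58 ± 0.24), H2ac15 (-5.14 ± 0.33) and Psmb10 (-4.72 ± 0.22) fell, with -5.72, -4.57 and -4.60 within slide 3, where Ldha came to -6.06. Igtp and Gdf1 were detected on 3 of 6 E8.5 arrays, and Mif, Psmb10, Gata2, Sdhd and Ddx21 on 1 of 3 E12.5 arrays. Hbb-bs, Alas2, Slc4a1, Nfe2, Tal1, Cdkn1b and Epor rose by 2.05, 2.90, 1.97, 2.16, 2.07, 1.27 and 0.84. Gata2 and Myb fell by 0.84 and 0.27, Kit was at least 2.32-fold and Runx1 at least 1.11-fold lower. Gata1 rose by 0.39 ± 0.16 (adjusted p = 0.033, 0.028 within slide 3), but not without E8.5 replicate 2, 5 or 6 or E12.5 replicate 2 or 3 (adjusted p = 0.051, 0.065, 0.061, 0.12 and 0.071). Hbb-bh1 (0.17), Hba-x (0.04), Hba-a1 (0.28), Klf1 (0.35) and Tfrc (0.17) did not pass, though Klf1 passed within slide 3 (0.84, adjusted p = 0.0096). The embryonic globins lie near the top of the signal range, where a further rise would be hard to see.

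Red cell membrane genes rose in 14 of 16 (14 alone, median 2.53; adjusted p = 7.7e-07, adjusted p = 0.064 with an estimated correlation), with Xk at 4.73 ± 0.22. Red cell enzymes rose in 12 of 14 with Car1 down (-1.83; the same alone, adjusted p = 0.0015, adjusted p = 0.09 with an estimated correlation), Ube2o at 4.13 ± 0.19. Heme synthesis had 11 up of 15 with Alas1 and Abcb6 down (-1.42 and -0.83; the same alone, adjusted p = 0.0094, adjusted p = 0.18 with an estimated correlation), Slc6a9 at 3.32 ± 0.18. Iron handling had 8 up of 13 with Pcbp1 and Ireb2 down (-1.06 and -0.75; the same alone, median 0.76; adjusted p = 0.041, adjusted p = 0.18 with an estimated correlation, 0.082 without E12.5 replicate 1), its median being -0.07 relative to all genes under median scaling. Ireb2 came to 0.60 within slide 3. Without E12.5 replicate 2 Abcb6 and Pcbp1 lost their calls (adjusted p = 0.13 and 0.094). With slide as a block they came to -0.33 and -0.30 (adjusted p = 0.21 and 0.27), and within slide 3 to the same values (0.35 and 0.39). Of 4 adult globins 3 rose (3 alone, adjusted p = 0.031, adjusted p = 0.18 with an estimated correlation), with Hbb-bt at 1.97 ± 0.20. Cell cycle inhibitors rose in 13 of 16 (13 alone, median 2.20; adjusted p = 1.1e-05, 0.0086 with an estimated correlation), with Ccng2 at 3.07 ± 0.16.

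Autophagy had 9 up of 18 with Atg3 and Atg4b down (-0.75 and -0.44; the same alone, adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation), with Sqstm1 at 3.52 ± 0.19. Atg3 lost its call without E8.5 replicate 1, 2 or 3 or any one E12.5 array (adjusted p = 0.076 to 0.11). With slide as a block Atg3 and Atg4b came to -0.07 and -0.36 (adjusted p = 0.82 and 0.067), though Atg4b passed within slide 3 (0.03). Antioxidant genes rose in 8 of 15 (8 alone, median 0.61; adjusted p = 0.022, adjusted p = 0.09 with an estimated correlation), Nqo1 being at least 7.89-fold higher, though their median was -0.42, and 0.04 relative to all genes, with no normalization between arrays. DNA replication fell in 23 of 24 (23 alone, median -2.60; adjusted p = 6.6e-11, 0.0086 with an estimated correlation), Ccne1 being at least 12.1-fold lower and Mcm5 at -3.55 ± 0.18. Mitosis fell in 16 of 23 with Bub1 up (1.25; the same alone, adjusted p = 0.00072, adjusted p = 0.21 with an estimated correlation), with Kif23 at -2.40 ± 0.21. Within ribosome assembly Rrp9 was at least 8.67-fold lower and Ddx21 fell by 3.86 ± 0.19.

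The metabolic and ribosomal protein lists were called downwards, with members that rose. The TCA cycle fell in 13 of 16 with Ogdh up (1.21; the same alone, adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation), with Sdhd at -2.16 ± 0.19. The respiratory chain fell in 19 of 30 with Cox6c up (1.16; the same alone, adjusted p = 0.0065, adjusted p = 0.21 with an estimated correlation), with Cox5a at -2.27 ± 0.18. Glycolysis fell in 11 of 17 (adjusted p = 0.028, adjusted p = 0.21 with an estimated correlation), with Tpi1 at -3.74 ± 0.17, while Slc16a3, Aldoc, Hk1, Pdk1 and Pfkfb3 rose by 0.42 to 1.51 (the same numbers alone). Pfkfb3 lost its call without E8.5 replicate 1, 2 or 3 or E12.5 replicate 3 (adjusted p = 0.053, 0.054, 0.056 and 0.23), and Pdk1 without E12.5 replicate 3 (0.077). Pfkfb3 came to 0.11 with slide as a block or within slide 3 (adjusted p = 0.47 and 0.62). Cytosolic ribosomal proteins fell in 14 of 24 with Rpl14 up (1.85; the same alone, median -0.73; adjusted p = 0.0055, adjusted p = 0.31 with an estimated correlation), but under cyclic loess their median was 0.72 (adjusted p = 0.086). Their member Rplp0 fell by 2.34 ± 0.17, and Rps24 was at least 11.1-fold lower on 1 probe while another of its probes rose. All 15 lists passed within slide 3 too, with adjusted p of at most 0.041. No marker list was called, the smallest adjusted p being 0.11 for visceral endoderm, which had 10 of 13 members down.

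Scaling changed the balance of this comparison. Median scaling shifted the median of all genes by 1.715 and gave 6929 higher and 1379 lower genes (83.4% higher against 47.2%), and no normalization between arrays, on slide 3 alone, shifted it by -0.463 and gave 1713 higher and 3976 lower (30.1% higher). Relative to those shifts DNA replication lay at -3.29 and -2.90, ribosome assembly at -3.76 and -3.05 and red cell membrane genes at 1.14 and 1.66. Under cyclic loess Cdkn1b, Myb, Gata1, Abcb6, Pcbp1, Ireb2, Atg3 and Atg4b came to 0.20, -0.17, 0.03, 0.09, -0.84, -0.12, 0.02 and -0.02, and Bub1, Slc16a3, Aldoc and Pfkfb3 to 0.21, 0.16, 0.08 and -0.14, none of them passing (adjusted p = 0.073 to 0.99).

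The E8.5 RNA was also measured after 2 rounds of amplification, on other samples. Compared with 1 round, 2532 genes were higher and 1631 lower with 2 rounds (n = 3 against n = 6, 8968 tested), led by Trmt6 (3.99 ± 0.18) and Ss18 (3.63 ± 0.22) upwards and H2ac12 (-6.80 ± 0.46), H2ac15 (-6.58 ± 0.34) and Atp5l (-6.48 ± 0.21) downwards. Slide 1 held all arrays with 2 rounds, so amplification and slide cannot be told apart. No gene list was called, the smallest adjusted p being 0.53. Within the E8.5 arrays of 1 round, 2314 genes were higher and 1373 lower on slide 3 than on slide 2 (n = 3 each, 8164 tested), although stage and amplification were the same. Rps13 (1.56 ± 0.19) and Hnrnpdl (1.55 ± 0.22) led upwards and Rpl36 (-2.67 ± 0.13), Nup62 (-2.22 ± 0.17) and Dek (-2.17 ± 0.23) downwards. Nfe2 came to -1.91 ± 0.13. Of all genes tested 3.87% differed more than 2-fold between the slides, against 39.5% between E8.5 and E12.5. From day to day the share was 5.92% at E9.5, 1.17% at E10.5, 4.29% at E11.5 and 25.2% at E12.5. The 3687 genes called between the slides outnumber those called at E9.5 (1824), E10.5 (197) and E11.5 (1086) against the stage before. These counts rest on unlike estimates of the spread. The slide count comes from a fit of the E8.5 arrays alone, and the others from the fit shared by all stages with 1 round. With only the 2 groups in the fit, 581 genes passed at E10.5 and 2852 at E11.5, and within slide 2 alone 1214 passed at E9.5. Those counts also lie below 3687, with other sets of genes tested.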

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

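The tests of detected probes at E12.5, of the authors' values for the slide difference and of a mixture at E7.5 replicate 2 were chosen only after the result was seen. Among the E8.5 arrays with 1 round of amplification, 9 of 147 genes had 1 array far from the other 5, measured as its gap to the nearest array over the whole range, and chance gives this in about 1 in 20 groups. Hba-a1 was lower on replicate 1 (13.15 against 13.82 to 14.04, gap 0.755), and so was Hba-x (13.34 against 13.90 to 14.19, gap 0.66). Acvr2b (7.87 against 8.37 to 8.64, gap 0.656) and Mdk (7.78 against 8.42 to 8.72, gap 0.683) were lower on replicate 1 too. On replicate 2 Dusp1 was higher (10.46 against 8.55 to 9.21, gap 0.655), as was Krt15 (5.27 against 4.40 to 4.63, gap 0.739). On replicate 3 Ltbp1 was higher (5.09 against 4.42 to 4.56, gap 0.781) and Rps24 lower (8.21 against 8.53 to 8.64, gap 0.752). On replicate 6 Slc25a37 was lower (9.65 against 9.90 to 10, gap 0.702).

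The E12.5 arrays had fewer detected probes than all others. A slide that is dim as a whole is excluded as the only cause, since the E8.5 array of slide 3 with the fewest detected probes had 1971 more than any E12.5 array. As part of the gap to arrays of other slides it is not excluded. The E8.5 arrays had 12541 to 12823 detected probes on slide 3 and 14176 to 15387 on slide 2. A loss on all probes alike is excluded as the only difference, with 23% of genes tested on slide 3 called higher at E12.5 with no normalization. As part of the difference it is not excluded, since changes with stage can raise genes on top of such a loss. In that fit 1713 genes were higher and 3976 lower, and the median of all genes lay at -0.463. The globin probes held at least 6.991% of the summed signal on the E12.5 arrays and at most 1.987% on the E8.5 arrays of slide 3, and whether this share is the cause cannot be told from these data. A biological fall in the number of transcripts as the cells mature could not be tested apart from it.

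The E8.5 arrays of slides 2 and 3 differed in 3687 genes. The normalization before deposit is not the whole cause, since 3664 genes differed with the authors' values, which share 1 distribution. The difference correlated at -0.045 with that between E8.5 and E7.5 over 7528 genes, so embryos shifted along that change are not the whole cause. That change was measured with 2 rounds of amplification, and the change from E8.5 to E9.5 was not compared. Other differences in age are therefore not excluded. Pairs of probes for the same gene correlated at 0.19 for the slide difference and at 0.65 for E11.5 against E10.5 within slide 4 (1051 pairs, standard deviations 0.52 and 0.50), which is consistent with hybridization differences that act on single probes.

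E7.5 replicate 2 lay between replicates 1 and 3 for 99.8% of 404 probes, and the highest other share among arrays with over 30 such probes was 84.1% (69 probes). Arrays with fewer such probes reached 100%. The share of 99.8% is consistent with a mixture of the material of both. Replicates 1 and 3 gave 99.6% of its signal variance, which does not single it out, since such fits gave 99.2% for E11.5 replicate 1 and 99.1% for E8.5 replicate 5. An average made by computation is excluded, since the other arrays gave only 34.1% of the variance among 26952 undetected probes, against up to 37% at E8.5. Pools in order of age could not be told from a mixture (correlation 0.13 over 11716 features).

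Splits of the same arrays into other groups show whether chance can be excluded. Chance is excluded, if each array is taken as independent of its slide, for E12.5 against E8.5 (6773 genes, highest other 2514, 1 of 84 splits as large), for amplification (4163, highest other 1452, 1 of 84) and for any stage (7289, highest other 2, 1 of 100). The other splits break up the slides, so effects of slide are not excluded by them, and amplification and slide cannot be told apart. Between E8.5 and E12.5 5626 genes passed within slide 3, where 10 splits are too few. For E9.5 against E8.5 2 of 84 splits were as large (1824, highest other 3149), the larger one being the E8.5 arrays of slide 3 against the rest, which follows the slide. Its lists reached 11 with 13 the highest other and 9 of 84 as large, so chance is not excluded there, while for the lists of E12.5 against E8.5 (15, highest other 16) 4 of 84 were as large. With 10 splits there are too few for E8.5 against E7.5 (1134 genes, highest other 0, 1 as large; 15 lists, highest other 4, 1 as large), E10.5 against E9.5 (197, 2, 1; 11 lists, 8, 1) and E11.5 against E10.5 (1086, 0, 1; 9 lists, 7, 1). The same holds for E12.5 against E11.5 (4737, 7, 1; 4 lists, 13, 7) and for the slides at E8.5 (3687, 0, 1).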

How the results depend on the processing

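The block for slide 3 against slides 2 and 4, slides 2 and 4 alone, slide 3 alone and no normalization between arrays were chosen only after results were seen. Over all settings, 264 values of named genes, 200 of them past the threshold, gave 5977 comparisons. Of these, 261 lost the call, 103 gained it and 33 turned direction with a call in either setting. The other 5580 kept their call with its direction or stayed uncalled. A change of sign in a value that stayed uncalled was not counted as a turn. Where a value changed, the cause was not tested. Signal over background limits genes near the detection level, above all at E12.5, where the fewest probes were detected.

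Counts of changed genes by setting were as follows, in the order of the comparisons. Median scaling gave 3129 for E9.5 against E8.5, 339 for E10.5 against E9.5 and 7911 for E12.5 against E11.5. Cyclic loess gave 445 for E10.5 against E9.5, 1631 for E11.5 against E10.5, 2166 for E12.5 against E11.5 and 3198 for E12.5 against E8.5. With no filter on dim probes the counts were 624 for E8.5 against E7.5, 122 for E10.5 and 719 for E11.5. A test against 1.5-fold gave 225, 335, 7, 48, 1908 and 3780 over the 6 comparisons. Array weights gave 1804 for E8.5 against E7.5, 1906 for E10.5 and 3177 for E11.5, and only the 2 groups in the fit gave 581 and 2852 for the last 2. The estimation of the array weights stopped before full convergence. Slide as a random block gave 18 for E10.5, slide as a fixed block 1764 for E11.5, and single slides 1214 for E9.5 and 2852 for E11.5. Averaged E8.5 arrays gave 507 for E10.5 and 1756 for E11.5, the block for slide 3 gave 507 and 1764, and slides 2 and 4 alone 817 and 2283.

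Replicate numbers do not pair the samples. Correlations of deviations of arrays with the same number ranged from -0.0504 to 0.10, -0.128 to 0.446, -0.00846 to 0.0963, -0.0771 to 0.0681, -0.14 to 0.0462 and -0.0302 to 0.065 over the 6 comparisons, and in none were all above 0.1. With the replicate number as a block 430 genes passed for E10.5 against E9.5 and 1678 for E11.5 against E10.5, and the other counts stayed within 1.5 times. Of the lists, iron handling at E8.5 against E7.5 (adjusted p = 0.059), TGF-beta at E9.5 (0.16) and iron handling at E12.5 against E8.5 (0.059) lost their calls with it. Progenitor genes (0.038) and cytosolic ribosomal proteins (0.046) at E9.5, endothelial markers at E10.5 (0.035), red cell enzymes at E11.5 (0.048), red cell enzymes and the TCA cycle at E12.5 against E11.5 (0.04 each) and erythropoietin signalling at E12.5 against E8.5 (0.046) gained one.

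Called lists moved as well. An estimated correlation left 0, 0, 2, 2, 1 and 3 lists over the 6 comparisons, and fry gave 19 for E9.5 against E8.5, 25 for E12.5 against E11.5 and 31 for E12.5 against E8.5. For E12.5 against E11.5, with 4 lists, normexp gave 11, median scaling 10, cyclic loess 13, the authors' values 11, no filter 13, only the 2 groups 10, slide as a random block 9, averaged E8.5 arrays 11 and the block for slide 3 9. Median scaling left 8 lists for E12.5 against E8.5, and cyclic loess left 6 for E9.5 against E8.5 and 4 for E11.5 against E10.5.

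Leaving out each array gave 217 to 1053 genes and 10 to 15 lists for E8.5 against E7.5, 1103 to 2154 and 8 to 12 for E9.5, 52 to 291 and 9 to 12 for E10.5, 430 to 790 and 6 to 9 for E11.5, 4174 to 4842 and 3 to 12 for E12.5 against E11.5, and 6238 to 6744 and 14 to 18 for E12.5 against E8.5. It gave 3492 to 4133 genes for amplification, 2893 to 3213 for the slides at E8.5 and 6991 to 7394 for any stage.

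Single genes turned direction at E12.5 against E11.5 under cyclic loess (Bub1 -0.16, Cdkn1b -0.07, Klf1 0.39), with the block for slide 3 (Klf1 0.22, Nfe2 1.84, Kit -0.75) and under median scaling (Myb 2.76, Runx1 2.95), where the median of all genes shifted by 1.90. At E12.5 against E8.5 they turned under median scaling (Gata2 1.41, Myb 2.16, Kit 0.60, Runx1 1.68, Car1 0.37, Alas1 0.23, Abcb6 0.57, Ireb2 0.58, Atg3 1.48, Atg4b 1.82) and cyclic loess (Abcb6 0.09, Atg3 0.02, Pfkfb3 -0.14). Median scaling shifted the median of all genes by 1.715 there, so of those 10 genes only Myb and Atg4b lie above it, and the other signs come from the shift. With no normalization, where the median of all genes shifted by -0.463, they were Epor -0.99, Runx1 0.02, Gata1 -1.40, Tfrc -1.50, Atg4b 0.15, Ogdh -1.08, Cox6c -0.08, Hk1 -0.57 and Pdk1 -0.88. Ireb2 came to 1.02 with only the 2 groups, 0.60 within slide 3 and 0.54 on slide 3 normalized alone. The authors' values were not used for the amplification comparison, since the authors normalized those arrays apart.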

Other observations

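The limits for both lists were written before their tests, the lists themselves after genes of their kind had appeared among the largest changes, and the spread over arrays, the histone test of the last step and the sex-linked reading were chosen only after results were seen. A stricter limit tried after the results, a camera p under 0.05 with an estimated correlation as well, would leave both explanations open and was not kept. Genes known from interferon responses moved in both directions late in the series. Rsad2 was at least 239-fold higher at E12.5 than at E8.5. Within slide 3, between E8.5 and E12.5 (n = 3 each), Ube2l6 came to 3.90, Trim25 to -1.29 and Bst2 to -0.88. Psmb10, also on the list, was among the largest decreases between these stages, and Ifitm2 among those between E8.5 and E9.5 (-2.62). Of all 17 genes of the list tested within slide 3, 11 rose and 5 fell. Among 10 such genes whose values had not been seen, 7 rose and 2 fell there, with a median of 1.05 (camera p = 0.005 in limma, 0.083 with an estimated correlation). Between E10.5 and E11.5 5 of 14 rose and none fell (median 0.45, camera p = 1.3e-06 in limma, 0.041 with an estimated correlation). Between E11.5 and E12.5 6 of the 14 rose and 5 fell (median 0.22, camera p = 0.52 in limma, 0.73 with an estimated correlation). The limits written beforehand, a median above 0.5 and a camera p under 0.05 within slide 3, were met, and the medians of the single E12.5 arrays were 0.76 to 1.18. This is consistent with an interferon response between E8.5 and E12.5, as a hypothesis, since members moved in both directions and no protein or signal was measured.

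The median histone cluster gene was not lower at E12.5 than at E8.5, where DNA replication genes fell by a median of 2.60. H2ac15 and H2ac12 were among the largest decreases at E12.5. Of 35 others tested within slide 3, 22 rose and 6 fell between E8.5 and E12.5 (median 1.05, camera p = 0.003 in limma, 0.5 with an estimated correlation). Over all arrays with 1 round 16 of 40 rose and 7 fell (median 0.43, camera p = 0.092 in limma, 0.66 with an estimated correlation). A median above -0.2 was the limit written beforehand against such a fall, and 1.05 lies beyond it by more than its spread over arrays (SE 0.35), with medians of 0.33 to 1.45 on the single E12.5 arrays. Within slide 3 the median member therefore did not fall under the main scaling, the only one used for this set. The median counts each member alike and leaves out H2ac15 and H2ac12, so a net fall of histone transcripts is not excluded. Nor does this median tell whether histone transcripts fell with the replication genes after E11.5, since it spans the earlier steps too. The set had medians of 0.45 at E10.5 and 0.52 at E11.5 against the stage before, with 1 and 10 of 40 members called higher. Camera gave p = 1.8e-07 and 1.1e-08 in limma, but 0.17 and 0.14 with an estimated correlation. The step to E10.5 also crosses slides and sources of cells. Between E11.5 and E12.5, a step that crosses slides, 15 of 40 fell and 6 rose (median -0.40, camera p = 0.037 in limma, 0.55 with an estimated correlation). With the block for slide 3 the median was 0.15 (SE 0.26 over arrays), with 10 higher and 7 lower, which leaves that step open.

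Sex-linked transcripts did not settle whether arrays held pooled or single embryos. Eif2s3y was not detected on the 3 E12.5 arrays (4.46, 4.48 and 4.37), and Xist read 7.95 to 8.54 there. A probe of Uty was detected on them (5.21, 5.78 and 5.83). That probe was also detected on E9.5 replicates 1 and 2 (4.98 and 5.49), where Eif2s3y was not, so its reading is unclear. On E11.5 replicates 1, 2 and 3 Eif2s3y read 5.71, 5.51 and 4.57, Uty 5.52, 5.44 and 5.04 and Xist 7.23, 7.06 and 7.90. Both Eif2s3y and Xist were thus detected on E11.5 replicates 1 and 2, which the label of single embryos does not explain. On the pools of E9.5 Eif2s3y was not detected on replicates 1 and 2 (4.43 and 4.40) and read 6.04 on replicate 3.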
